A study of Homo sapiens with 4 samples.

How the data were processed

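RNA of cells labelled OPM2 and KMS11 was measured on 4 whole-transcript arrays, 1 for each combination of line and treatment (none, or KPT-9274 for 48 h). Per the labels' protocols, total RNA was extracted with a miRvana kit and made into biotinylated sense-strand DNA with the WT Plus kit. The deposited table holds log2 signal values made by the authors with the Transcriptome Analysis Console, per the submitters' processing notes. The summarization method, the normalization between arrays and the genome build are not given in the sources used here. The log2 scale was taken from the range of the values, 2.49 to 19.74 with 2 decimals, and no centring was seen in the array medians. Every value column of the table belongs to a labelled sample, so 0 columns were left aside. The number of arrays limits the precision.

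Each of the 65528 transcript clusters was named through a table of the array's annotation. Of these, 22755 had 1 gene symbol, 1389 had several and were named for none of them, and 41384 were unnamed here. Symbols were updated with a table of human genes of assembly GRCh38.p14, used for names alone: 20539 clusters by gene number, 1916 by current symbol and 296 by an older symbol, while 4 kept the file's name. Where a gene had several clusters (345 genes), the cluster with the highest mean over the 4 arrays stood for it. Of 22393 genes the 25% with the lowest mean were left out (a mean log2 signal of at most 5.40), which left 16790.

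Values were analysed as deposited in R 4.3.3 with limma 3.58.1. A linear model with cell line and agent was fitted to the 4 arrays (lmFit, eBayes, 1 residual degree of freedom and 2.79 prior degrees of freedom), with two-sided tests and Benjamini-Hochberg adjustment at 0.05. The cell line was the block of the treatment contrast, since the arrays of a line share its cells. The line contrast came from the same fit. Background was the 95th percentile of olfactory receptor genes on each array, a measure chosen after the data were seen, and changes of named genes that read under it are bounds against it. Within a line there is no test, and differences and counts of genes at least 2-fold apart describe those arrays. The line-specific part of the response is the model's only residual and could not be tested.

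Gene lists (39, of which 6 hold cell type markers) were fixed before the data were examined. The 37 lists with at least 5 tested genes entered camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Mitochondrial genome transcripts had 0 measured genes and immunoglobulin genes had 3 tested genes, so neither was tested. The result of 1 tested list is not reported here. Per line, a list's median change was set among 10000 random lists of the same size drawn within 50 bins of signal level, and 95% intervals come from 10000 bootstrap resamples of members. With the preset correlation 2 lists were higher and 7 lower after treatment. With the estimated correlation 0 passed, and 0 passed by fry, whether for a change one way or for a change in either direction. The same camera tests on the line contrast were chosen after the line differences were seen.

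Genes were named by a rule fixed in advance. It takes, for the treatment, the 12 genes higher and 12 lower past the threshold, or, where too few pass, those with the largest value of the smaller of both lines' changes. It adds PAK4 and NAMPT, and from each list up to 4 members past the threshold or else 2 by the same ranking. It also adds up to 5 genes at least 2-fold apart in opposite directions, NSD2, FGFR3, MAF, CCND2 and the 5 largest line differences each way, and the 5 largest changes each way within a line. Uncharacterised genes and small RNAs were named only within the top 12.

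The fit was tested on simulated data for the treatment contrast over 16790 genes, with 200 changed genes in each of 10 runs. It recovered 0.2% of genes changed 2-fold, 18.2% at 4-fold, 83.0% at 8-fold and 93.6% at 16-fold, with 81 false calls over all runs. These shares hold only for data with that many large changes, since such genes ease the adjustment for each other. On the real arrays CREBRF had log2 changes of 4.08 and 3.50 and a limma adjusted p of 0.325. The shares therefore do not tell how large a change the real comparison could detect. The simulated noise was drawn for each gene on its own, so list members were not correlated. Of 370 tests of unchanged lists 0 were called, which does not tell how often lists of correlated genes would be. A shift of 0.5 in the G2/M list was called in 10 of 10 runs with the preset correlation and in 0 of 10 with an estimated correlation. The latter test has 1 residual degree of freedom here and could hardly call any list. Its failures below therefore do not decide for or against a list.

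Alternatives were quantile normalization, median centring, no filter or a filter at 50%, the mean of a gene's clusters or every cluster on its own, a trended and robust prior, no line block, a test against 1.5-fold (treat), a 1.5-fold count threshold, leaving out each line, and cyclic loess, which was added after the level-dependent difference between the OPM2 arrays was seen. Clusters without a gene symbol entered no comparison of genes. Scanner files were not analysed here.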

Results

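RNA from cell cultures labelled OPM2 and KMS11, the names of human myeloma lines, was measured on 4 whole-transcript expression arrays. Each line has 1 untreated array and 1 array of cells treated for 48 h with KPT-9274, a compound known to inhibit the kinase PAK4 and the NAD salvage enzyme NAMPT. Each array gives 65528 transcript clusters, of which 22755 carry a single gene symbol. They stand for 22393 genes, and 16790 of these were tested after the dimmest were left out. The median log2 signal was 5.75 on the OPM2 control array, 6.07 on the treated OPM2 array, 5.68 on the KMS11 control array and 5.76 on the treated KMS11 array. The Pearson correlation across clusters was 0.971 for the OPM2 arrays and 0.978 for the KMS11 arrays, and 0.906 to 0.927 between lines. With 1 array per line and treatment, a change within a line has no replicate. The 2 lines served as the replicates of the treatment, nothing in the labels tells of separate cultures, and p-values of single genes measure only the spread between these 4 arrays. Camera with the preset correlation sets list members against the other genes. Its p-values rest on the number of genes, treated as nearly independent, and not on replicate cultures.

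The first comparison sets the lines against each other, over control and treated arrays together. Several genes central to plasma cells read far lower on the arrays labelled KMS11. IRF4, a transcription factor that plasma cells depend on, read 14.26 on the OPM2 control array and 6.75 on the KMS11 control array. PRDM1, which drives plasma cell differentiation, read 12.47 and 5.99, the B lineage coactivator POU2AF1 10.47 and 5.39, the plasma cell receptor TNFRSF17 10.68 and 5.28, and the immunoglobulin joining chain JCHAIN 16.99 and 9.94. The 95th percentile of 392 olfactory receptor genes, taken as background, was 6.81 on the OPM2 control array and 6.45 on the KMS11 control array, where IRF4 and JCHAIN stayed above it. The KMS11-labelled arrays also carried genes of the erythroid and myeloid lineages. GATA1, the erythroid and megakaryocytic transcription factor, read 15.90 on the KMS11 control array and 5.24 on the OPM2 control array, the red cell membrane protein RHAG 14.37 and 5.51, the myeloid gene MS4A3 16.14 and 5.12, the histamine-forming enzyme HDC 15.02 and 5.36, and GTSF1 14.89 and 5.63.

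By limma, 1808 genes were higher in the KMS11-labelled arrays and 1391 higher in OPM2. MS4A3, GATA1, HDC, GTSF1 and RHAG were not above background on either OPM2 array, so their differences are bounds against background. They were at least 8.64 log2 units for MS4A3, 8.63 for GATA1, 7.69 for HDC, 8.01 for GTSF1 and 7.53 for RHAG. The limma test used the values as deposited, not these bounds, and gave adjusted p = 0.00370 for each. Among genes higher in OPM2 were the kappa light chain variable gene IGKV1D-37 with a difference of -10.06. Others were not above background on either KMS11-labelled array: IGKV3D-15 was higher by at least 7.80, IGKV3D-7 by at least 7.14, the G protein regulator RGS1 by at least 7.39 and the imprinted gene PEG10 by at least 6.99. The genes set in advance as a check of the labels were the myeloma translocation targets. MAF, which KMS11 cells are known to overexpress, read 12.11 on the OPM2 control array and 5.68, under background, on the KMS11 control array. MAF was lower by at least 4.99 on the KMS11-labelled arrays, and limma gave adjusted p = 0.00933 for the unbounded difference of -5.72. FGFR3, overexpressed in both lines by a known translocation, read 13.55 and 7.99 (difference -5.31, adjusted p = 0.00440), its neighbour NSD2 12.39 and 10.84 (difference -1.16, adjusted p = 0.0624), and CCND2 14.69 and 12.23 (difference -2.50, adjusted p = 0.00928). NSD2 passed under quantile normalization (adjusted p = 0.0274), with the lowest 50% of genes left out (0.0348) and after cyclic loess (0.0249). The MAF value, the low FGFR3 level and the erythroid and myeloid genes go against the KMS11 label. FGFR3, NSD2 and CCND2 lay above background there, but FGFR3 at 7.99 on the control array was far under its OPM2 level. The arrays are therefore called KMS11-labelled here, and no statement below rests on their being myeloma cells. IRF4, PRDM1, POU2AF1, TNFRSF17 and JCHAIN were named after their values were seen.

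Lists fixed in advance showed the same split, though not independently of the genes above. IRF4, PRDM1, POU2AF1, TNFRSF17 and JCHAIN belong to the plasma cell list and GATA1 to the erythroid list. Of 25 plasma cell identity genes, 13 were lower in the KMS11-labelled arrays and 0 higher past the test over all genes, 12 did not pass, and 18 were lower and 1 higher when adjusted over the list alone (median difference -1.74, camera adjusted p = 4.85e-06). Of the 25, 20 lay above background on the OPM2 control array, and 14 on the treated OPM2 array, whose background was 7.65, and on each KMS11-labelled array. Of 11 monocyte and myeloid markers 6 were higher, LYZ by at least 6.32 and TYROBP by at least 5.77 among them, and 5 did not pass (median difference 1.24, camera adjusted p = 0.0106; 6 higher adjusted over the list alone). Of 10 erythroid and megakaryocyte markers 4 were higher and 6 did not pass (median difference 1.16, camera adjusted p = 0.0112; 6 higher adjusted over the list alone). Cytosolic ribosomal proteins (median difference 0.56, camera adjusted p = 1.07e-05), cholesterol synthesis genes (0.998, camera adjusted p = 0.0112) and DNA repair genes (0.41, camera adjusted p = 0.0398) were also higher as lists in the KMS11-labelled arrays. Antigen presentation genes (-0.96, camera adjusted p = 0.000630) and heat shock genes (-0.67, camera adjusted p = 0.0118) were lower. With an estimated correlation none of the 37 lists passed (adjusted p = 0.981 for each list named here), a test that had 1 residual degree of freedom and could hardly call any list. The DNA repair call was also lost under quantile normalization (adjusted p = 0.157), with the lowest 50% of genes left out (0.197) and after cyclic loess (0.147), the cholesterol call with the lowest 50% left out (0.0594), and the myeloid call without a filter (0.131).

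**Figure D1:**
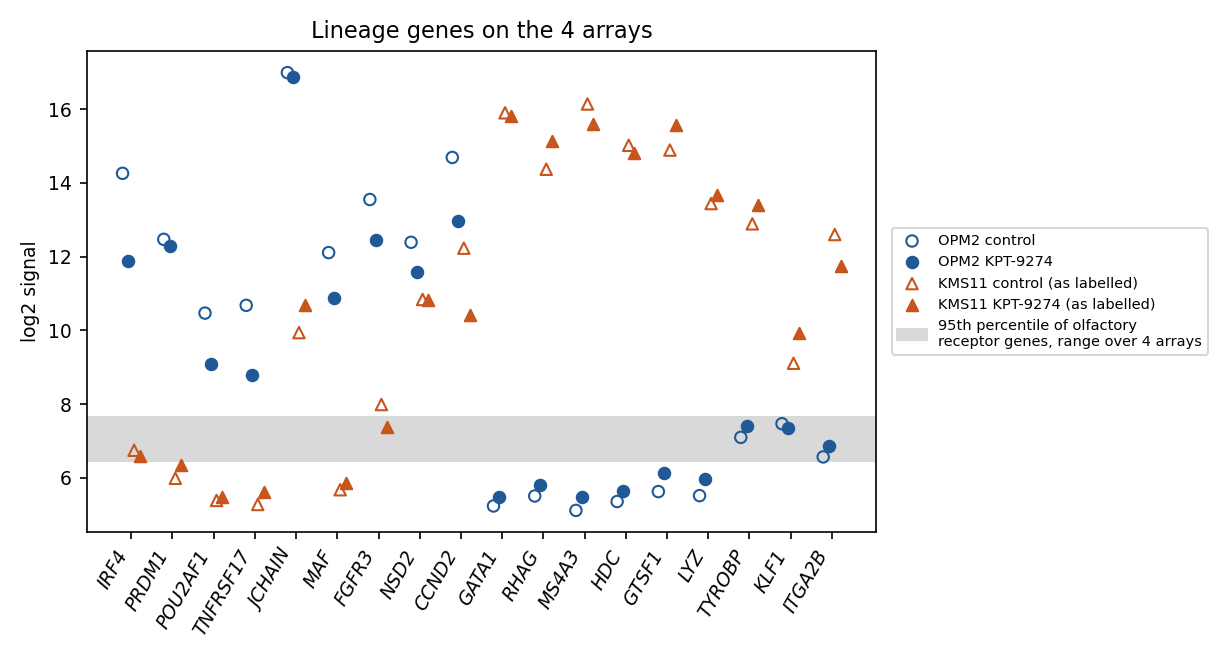
The log2 signal of 18 genes (x axis) is plotted for each of the 4 arrays, circles for OPM2 and triangles for the KMS11-labelled arrays, open for control and filled for KPT-9274, over a grey band for the 95th percentile of olfactory receptor genes on the 4 arrays. IRF4, PRDM1, POU2AF1, TNFRSF17 and MAF lie in or under the band on the KMS11-labelled arrays, where GATA1, MS4A3 and HDC lie between 14.82 and 16.14.

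The main comparison asks how transcripts of these cells after 48 h of KPT-9274 differed from those of the untreated controls. The labels give no time for the controls, so time in culture cannot be told apart from the compound. Below, paired values are log2 changes, treated minus control, with OPM2 before the KMS11-labelled arrays. Where 1 of the 2 arrays of a line read under background, the change is a bound against background (at least), and where both did, none is given for that line. The regulator CREBRF, which restrains the CREB3 family, was higher by 4.08 and 3.50. HBP1, a repressor of cell cycle genes, was higher by 3.57 and 2.02, KLHL24 by 3.57 and 1.82, the arrestin-domain gene ARRDC3 by 1.79 and 3.95, RASGEF1B by 2.62 and at least 2.07, the splicing kinase CLK1 by 2.25 and 1.67, the MAP kinase phosphatase DUSP10 by 1.59 and 1.71, and the mitotic genes ANLN and KIF18A by 1.60 and 1.70 and by 1.58 and 2.14. The other genes of that group were MIR3662 (at least 1.16, and 1.77), MIR4742 (1.66 and 2.07) and ADAM20P1, which was not above background on any array. On the other side, MIR142, the host of a blood cell microRNA, was lower by at least 4.38 and by 2.71, and MIR4521 by at least 2.80 and by 2.92. The GPI anchor enzyme PIGW was lower by at least 1.38 and 2.40 and TEX15 by at least 0.70 and by 2.51. BRI3BP had values of -2.45 and -2.04 and cyclin D2 (CCND2) -1.73 and -1.82.

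The same group held the nuclease EXO1 (-1.82 and -1.72), the single-strand binding protein NABP1 (-1.88 and -2.27), the clamp loader component CHTF8 (-1.93 and -2.11), NCOA5 (-1.79 and -2.37), TRMT61B (-1.79 and -2.01) and LINC00294 (lower by at least 0.26 and 1.04). Over the 16790 genes the changes of the lines had a Pearson r of 0.359 and a Spearman rho of 0.338, computed across genes, which are not independent replicates. At least 2-fold changes in both lines were counted for 55 genes higher and 198 lower, against 6.90 and 40.9 for independent lists, and 16 genes went at least 2-fold in opposite directions, against 33.8. The counts moved with the scaling, to 90 higher and 108 lower under quantile normalization, 83 and 130 under median centring, and 123 lower after cyclic loess. With changes taken as bounds against background, 49 genes were at least 2-fold higher and 158 lower in both lines, against 4.38 and 29.7 for independent lists. Of the 55 and the 198, 8 and 14 were small RNAs or uncharacterised genes. Within OPM2 421 genes were at least 2-fold higher and 925 lower (553 lower under quantile normalization and 569 after cyclic loess), and within the KMS11-labelled arrays 275 and 743.

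No gene passed limma's test over both lines: 0 higher and 0 lower at an adjusted p below 0.05, with 0.325 the smallest adjusted p. At an unadjusted p below 0.05 there were 666 higher and 1453 lower genes, 2119 in all, against 839.5 by chance, and limma with a 1.5-fold threshold (treat) also gave 0 and 0, with 90 and 323 at an unadjusted p below 0.05. That split moved with the scaling, to 1174 and 1004 under median centring and 1089 and 1153 under quantile normalization. Single genes are therefore given as values, and group statements rest on the list tests.

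**Figure D2:**
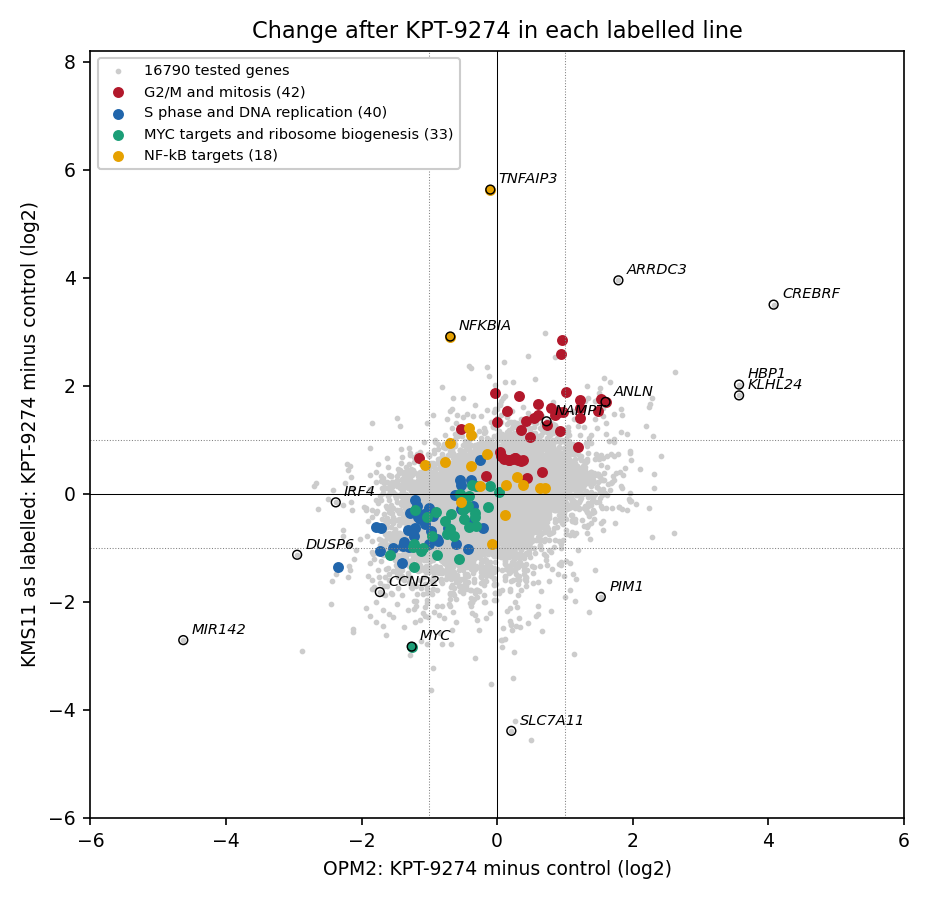
Each point is a gene, with its log2 change (treated minus control) in OPM2 on the x axis and in the KMS11-labelled arrays on the y axis, grey for the 16790 tested genes and coloured for members of 4 lists, with dotted lines at 2-fold. CREBRF lies at 4.08 and 3.50, G2/M genes lie toward the upper right, S phase genes toward the lower left, and TNFAIP3 at -0.10 and 5.63.

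Of the compound's known targets, NAMPT was higher by 0.73 and 1.34. PAK4 was higher by 0.22 on the KMS11-labelled arrays. In OPM2 it read 6.94 and 6.97, the latter under the raised background of the treated array, so its change there cannot be read. Among the 12 tested genes of the PAK family and NAD salvage 4 were higher in both lines and 2 lower, NADSYN1 with -0.65 and -0.46, and the list medians were 0.01 and 0.14 (camera adjusted p = 0.521), the OPM2 median being -0.01 after cyclic loess. NAD-consuming enzymes had medians of -0.07 and 0.13 (camera adjusted p = 0.812), with 7 of 18 higher and 5 lower in both lines, PARP14 (-1.27 and -0.72) and PARP4 (-0.83 and -0.69) among the latter; the OPM2 median was 0.04 under median centring, and the mean and the test pointed down while the median over both lines was 0.05. No member of either list passed over all genes, and 0 and 0 passed adjusted over the list alone.

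Cell cycle genes split by phase. The G2/M and mitosis list rose: 37 of 42 members were higher in both lines and 0 lower, with medians of 0.46 and 1.29, and camera gave adjusted p = 1.04e-16. The kinase TTK was higher by 1.53 and 1.75 beside ANLN, and 7 members were at least 2-fold higher in both lines. The S phase and DNA replication list fell: 36 of 40 members were lower in both lines and 0 higher, with medians of -1.01 and -0.58 and camera adjusted p = 3.64e-15. Cyclin E2 (CCNE2) had -2.35 and -1.36 and the origin licensing factor CDC6 -1.40 and -1.28. The DNA repair list fell too, with 22 of 29 members lower in both lines and 2 higher, medians of -0.50 and -0.53, camera adjusted p = 3.69e-07, and BRCA1 at -1.73 and -1.66. With an estimated correlation each of these 3 lists had adjusted p = 0.894, so the calls rest on the preset correlation of 0.01. The test with an estimated correlation had 1 residual degree of freedom and called a planted G2/M shift in 0 of 10 simulated runs. It therefore does not decide whether these calls hold. No member passed over all genes, while 14 G2/M, 15 S phase and 6 DNA repair genes passed adjusted over the list alone.

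Replication-dependent histones were not called (medians -0.30 and 0.43, camera adjusted p = 0.363; 7 of 17 higher and 3 lower in both lines). H2AC6 was higher by 0.58 and 1.30, H2BC18 was not above background on any array, and 23 of the 40 listed histones were measured only in clusters shared with other genes. CDK inhibitors and cyclin D genes had medians of -0.31 and 0.14 (camera adjusted p = 0.521; 5 of 12 higher and 5 lower in both lines), with CCND3 at -0.81 on the KMS11-labelled arrays, and not above background in OPM2, beside CCND2. The p53 target list had medians of -0.07 and -0.16 (camera adjusted p = 0.561; 6 of 24 higher and 8 lower in both lines), the death receptor TNFRSF10A at -1.27 and -1.73 and TP53INP1 at 1.72 and 0.96, and its OPM2 median turned to 0.03 under median centring. Adjusted over the list alone, 0 histones, 1 CDK inhibitor or cyclin D gene and 4 p53 targets passed.

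MYC was lower in both lines, with values of -1.26 and -2.83. The list of MYC targets and ribosome biogenesis fell, with 28 of 33 members lower in both lines and 1 higher, medians of -0.64 and -0.46, camera adjusted p = 1.05e-11, and the ribosome assembly factor RRS1 at -1.23 and -1.36. The MAPK output list fell, with 10 of 16 members lower in both lines and 5 higher, medians of -0.84 and -0.63, camera adjusted p = 0.000358, the ERK phosphatase DUSP6 lower by at least 2.23 and 0.57 and the RAS pathway inhibitor SPRED1 by at least 1.14 and by 1.54. Of the 16, 9 lay above background on each control array, 1 on the treated OPM2 array and 4 on the treated KMS11-labelled array. Most of these changes run into background. The MAPK median over both lines depended on the filter: it was -0.745 as deposited, -1.205 with the lowest 50% of genes left out and -0.48 without a filter. Cytosolic aminoacyl-tRNA synthetases fell as a list (10 of 19 lower and 1 higher in both lines, medians -0.29 and -0.70, camera adjusted p = 0.00733), with FARSB at -1.19 and -0.70 and IARS1 at -0.49 and -1.33. With an estimated correlation each of these 3 lists had adjusted p = 0.894. Adjusted over the list alone, 10 MYC list, 8 MAPK and 0 synthetase genes passed. The synthetase call was lost with the lowest 50% of genes left out (adjusted p = 0.0988) and under quantile normalization (adjusted p = 0.0773).

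The ATF4 and integrated stress response list was not called (camera adjusted p = 0.117), with medians of 0.05 and -0.52 and 2 of 31 members higher and 11 lower in both lines. It was called lower without a filter (adjusted p = 0.0207) and without the line block (adjusted p = 0.0346). The amino acid transporter SLC7A5 had -0.97 and -3.63, and the eIF2 phosphatase subunit PPP1R15A was higher by 1.72 and 1.47; 1 member passed adjusted over the list alone. Wnt and beta-catenin targets had medians of 0.01 and 0.11 (camera adjusted p = 0.809; 6 of 13 higher and 2 lower in both lines, ZNRF3 lower by at least 0.23 and by 0.46), which turned to -0.21 and -0.01 after cyclic loess, and their mean and test pointed down. Cytosolic ribosomal proteins had medians of -0.04 and 0.09 (camera adjusted p = 0.737; 13 of 36 higher and 12 lower in both lines, RPS12 at 0.30 and 0.29 and RPL10A at 0.30 and 0.26), the OPM2 median being 0.14 under quantile normalization. Immediate early genes had medians of -0.05 and 0.09 (camera adjusted p = 0.809; 5 of 16 higher and 4 lower in both lines, KLF6 at 0.83 and 1.70 and JUND lower by at least 0.01 and by 1.20), with 0.05 in OPM2 under median centring and a mean and test that pointed down. No Wnt, ribosomal or immediate early gene passed adjusted over the list alone, that is 0 in each list. Background was passed by 4 of the 13 Wnt genes on the OPM2 control array, 2 on the treated one and 5 on each KMS11-labelled array. For the 16 immediate early genes it was 9 and 3 in OPM2, control before treated, and 9 and 7 on the KMS11-labelled arrays.

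The autophagy and lysosome list rose: 18 of 30 members were higher in both lines and 2 lower, with medians of 0.14 and 0.40 and camera adjusted p = 0.000239. The autophagy initiation factor ATG14 was higher by 1.20 and 0.92 and the folliculin partner FNIP2 by 1.07 and 0.86. The fatty acid synthesis list fell, with 9 of 16 members lower in both lines and 3 higher, medians of -0.67 and -0.14, camera adjusted p = 0.0287, fatty acid synthase FASN at -1.83 and -1.12 and the elongase ELOVL6 at -1.42 and -1.28. The ER unfolded protein response list fell, with 15 of 35 members lower in both lines and 5 higher, medians of -0.35 and -0.04, camera adjusted p = 0.0417, XBP1 at -1.40 and -1.14 and ERO1A at -1.51 and -0.65. With an estimated correlation each of these 3 lists had adjusted p = 0.894. Adjusted over the list alone, 0 autophagy, 3 fatty acid and 0 ER genes passed. The ER call was lost under quantile normalization (adjusted p = 0.353), where the KMS11-labelled median was 0.07 (0.08 under median centring), and the fatty acid call was lost there too (adjusted p = 0.0941). Among random lists matched on signal level, the median over both lines lay at the 35.6th percentile for the ER list and the 15.97th for the fatty acid list.

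Other metabolic and stress lists were not called on the values as deposited with the filter at 25%, with 0 members past the test adjusted over the list alone in each. Cholesterol synthesis genes had medians of -0.73 and 0.19 (camera adjusted p = 0.204; 1 of 20 higher and 5 lower in both lines, FDPS at -0.94 and -0.56 and LSS at -1.04 and -0.33), and were called lower without a filter (adjusted p = 0.0305). Glycolysis and hypoxia genes had medians of -0.34 and -0.01 (camera adjusted p = 0.299; 4 of 27 higher and 11 lower, KDM3A at 1.47 and 1.22 and HK2 at -0.79 and -1.10), the KMS11-labelled median being 0.04 under quantile normalization. Oxidative phosphorylation genes had medians of -0.14 and 0.22 (camera adjusted p = 0.536; 8 of 41 higher and 3 lower, UQCRB at 0.49 and 0.88 and SDHD at 0.46 and 0.43), with 0.07 in OPM2 under quantile normalization, which also called the list (adjusted p = 0.00304), as cyclic loess did (adjusted p = 0.0110). Proteasome genes had medians of -0.34 and 0.26 (camera adjusted p = 0.630; 2 of 34 higher and 4 lower, PSMA3 at -0.38 and -0.74 and PSMD12 at -0.33 and -0.65). NRF2 targets had 0.21 and 0.19 (camera adjusted p = 0.115; 8 of 19 higher and 1 lower, FTL at 0.59 and 0.71 and GCLC at 0.43 and 0.36). Heat shock genes had 0.00 and 0.03 (camera adjusted p = 0.894; 6 of 16 higher and 5 lower, BAG3 higher by 0.45 and at least 0.90 and DNAJB4 at 1.58 and 0.38), with 0.11 in OPM2 under quantile normalization and -0.02 in the KMS11-labelled arrays after cyclic loess. BCL2 family genes had -0.05 and -0.16 (camera adjusted p = 0.521; 4 of 15 higher and 7 lower, BID at -0.93 and -0.83 and BAK1 at -0.18 on the KMS11-labelled arrays and near background in OPM2), with 0.06 in OPM2 under quantile normalization.

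**Figure D3:**
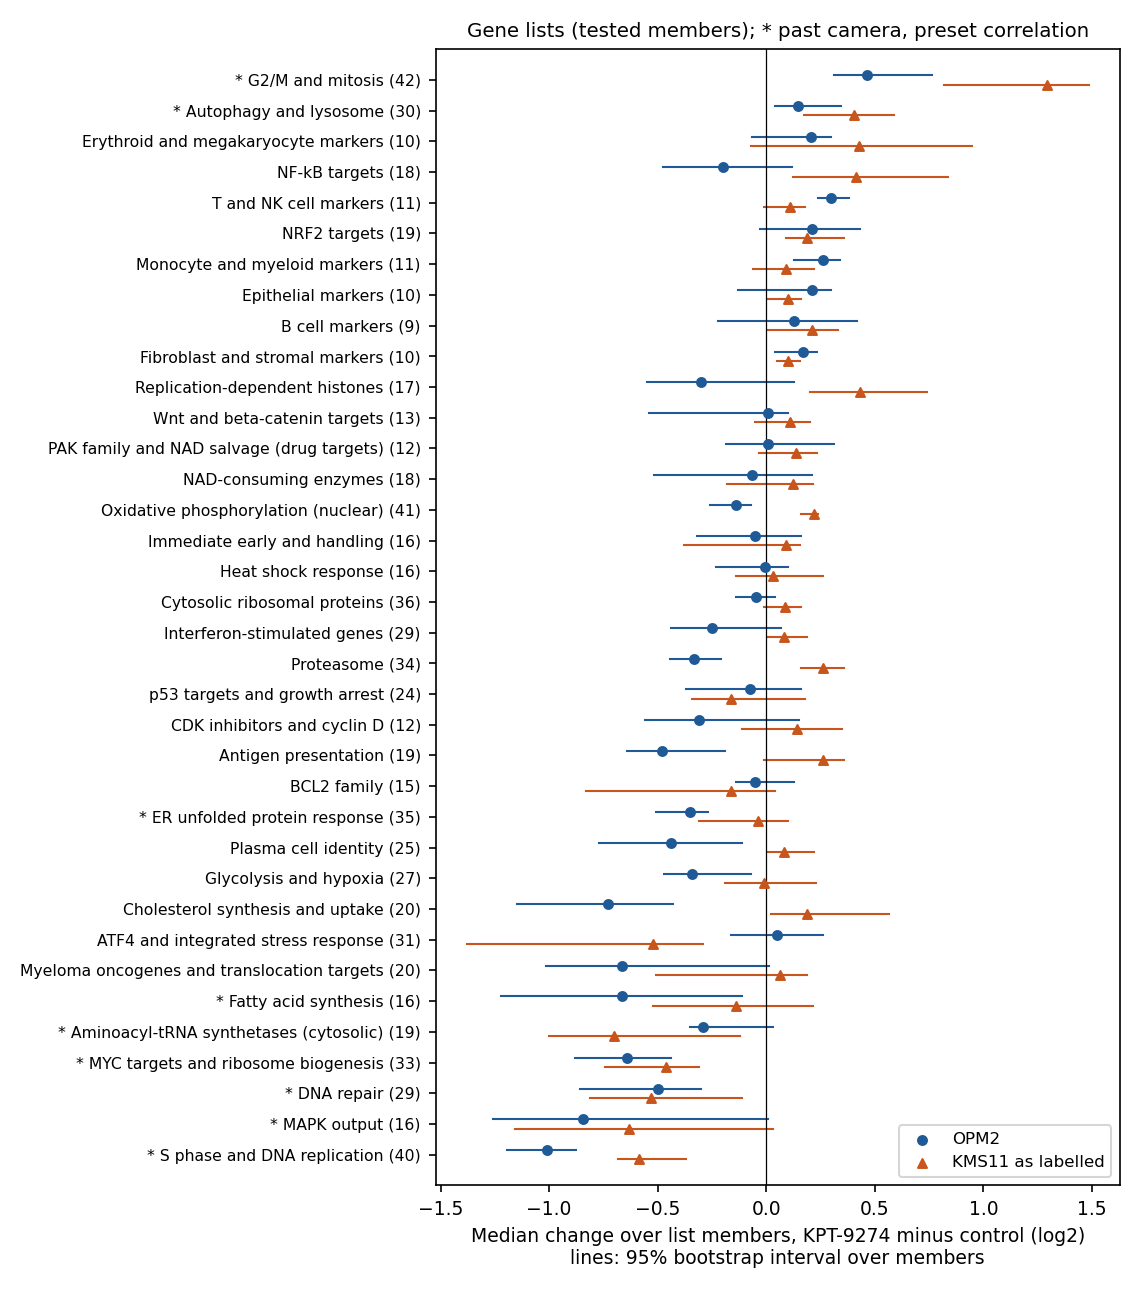
Each fixed list reported here (y axis, tested members in brackets) has the median log2 change of its members on the x axis, circles for OPM2 and triangles for the KMS11-labelled arrays, with 95% bootstrap intervals over members as lines and a star where camera with the preset correlation passed. G2/M genes lie highest at 0.46 and 1.29 in both lines. S phase genes lie lowest in OPM2 at -1.01 and aminoacyl-tRNA synthetases lowest on the KMS11-labelled arrays at -0.70.

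Lineage and immune lists were not called for the treatment on those values, and most differed in sign between the lines. Plasma cell identity genes had medians of -0.44 and 0.08 (camera adjusted p = 0.386; 6 of 25 higher and 5 lower in both lines), IRF4 at -2.38 and -0.16 and the IL-6 receptor chain IL6ST at 0.91 and 1.14. Myeloma oncogenes and translocation targets had -0.66 and 0.06 (camera adjusted p = 0.115; 5 of 20 higher and 8 lower), the latter median turning to -0.01 after cyclic loess, and were called lower without a filter (adjusted p = 0.0180). NF-kB targets had -0.20 and 0.41 (camera adjusted p = 0.340; 5 of 18 higher and 2 lower, PLAU and CCL3 not above background on any array). Interferon-stimulated genes had -0.25 and 0.08 (camera adjusted p = 0.487; 7 of 29 higher and 6 lower, SAMD9L at -1.36 and -1.07 and DTX3L lower by at least 0.60 and by 0.52), and antigen presentation genes -0.48 and 0.26 (camera adjusted p = 0.324; 1 of 19 higher and 6 lower, CIITA lower by at least 2.36 and by 0.28 and TAP2 at -1.05 and -0.52). Adjusted over the list alone, 1 myeloma gene, CCND2, and 0 genes of each other list passed. On the OPM2 control, treated OPM2, KMS11 control and treated KMS11-labelled arrays, 11, 9, 11 and 12 of the NF-kB targets lay above background. For interferon-stimulated genes it was 15, 8, 18 and 18, and for antigen presentation genes 17, 10, 15 and 15. The OPM2 medians of these lists therefore rest in part on members that cannot be read there.

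No list of markers of other cell types was called for the treatment on those values, and many members lay under background. On the OPM2 control, treated OPM2, KMS11 control and treated KMS11-labelled arrays, background was passed by 1, 0, 4 and 6 of the erythroid and megakaryocyte markers, 5, 1, 8 and 8 of the myeloid, 1, 1, 4 and 4 of the T and NK cell, 2, 0, 4 and 4 of the B cell, 4, 2, 4 and 3 of the epithelial and 0, 0, 1 and 1 of the stromal markers. In OPM2 their medians mostly describe background. On the KMS11-labelled arrays that holds less for the myeloid markers, with 8 of 11 above it on each array. The same goes for the erythroid and megakaryocyte markers on the treated array, with 6 of 10 above it. Erythroid and megakaryocyte markers had medians of 0.21 and 0.42 (camera adjusted p = 0.138; 3 of 10 higher and 1 lower in both lines, ALAS2 higher by 1.18 and GP9 by at least 0.29 on the KMS11-labelled arrays), the KMS11-labelled median lying at the 99.95th percentile of matched random lists and the OPM2 median being -0.06 after cyclic loess. Monocyte and myeloid markers had 0.26 and 0.09 (camera adjusted p = 0.230; 7 of 11 higher and 1 lower, TYROBP at 0.50 and LYZ at 0.22 on the KMS11-labelled arrays). T and NK cell markers had 0.30 and 0.11 (camera adjusted p = 0.0842; 7 of 11 higher and 0 lower, CD7 at 0.51 on the KMS11-labelled arrays and THEMIS at 0.88 in OPM2), and were called higher without a filter (adjusted p = 0.0126). B cell markers had 0.13 and 0.21 (camera adjusted p = 0.241; 7 of 9 higher and 1 lower, BCL6 not above background and BANK1 at 0.32 on the KMS11-labelled arrays), epithelial markers 0.21 and 0.10 (camera adjusted p = 0.393; 6 of 10 higher and 1 lower, KRT8 at 0.43 and 0.24 and CLDN3 near background) and stromal markers 0.17 and 0.10 (camera adjusted p = 0.239; 7 of 10 higher and 0 lower, TAGLN and CXCL12 not above background on any array). The B cell and stromal medians in OPM2 were -0.05 and -0.07 after cyclic loess, the stromal median of the KMS11-labelled arrays was -0.02 there, and 0 genes of any marker list passed adjusted over the list alone.

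The lines also differed in their largest changes, which no test can compare with 1 array per group. On the KMS11-labelled arrays the NF-kB inhibitors TNFAIP3 and NFKBIA were higher by 5.63 and 2.91, against -0.10 and -0.69 in OPM2, and ASB12, not above background in OPM2, by at least 2.27. The cystine transporter SLC7A11 was lower there with -4.39, and the glutamine transporter SLC38A1 with -3.53, against 0.21 and -0.09 in OPM2. CHRM3-AS2 and ADAMTS1 were lower there with -4.55 and -3.42 and were not above background in OPM2, so no response can be compared. In OPM2 PELI2 was higher by 2.42, against 0.70, and RGS16 and the peroxisomal transporter ABCD2 were lower by at least 1.88 and 2.11. Neither was above background on the KMS11-labelled arrays, where it had no room to fall. The kinase PIM1 (1.53 and -1.91), STON2 (1.44 and -1.41), STX11 (lower by at least 1.03, and 1.41), MTMR10 (-1.85 and 1.31) and the sterol demethylase CYP51A1 (-1.43 and 1.26) went at least 2-fold in opposite directions.

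The treated OPM2 array differed from its control with signal level. Across deciles of the tested genes by signal the median OPM2 change went from 0.25 in decile 1, the dimmest, to -0.31 in decile 8 and -0.16 in decile 10, and on the KMS11-labelled arrays from 0.12 to -0.04 and 0.02. Olfactory receptor genes had a median change of 0.49 in OPM2 and 0.14 on the KMS11-labelled arrays. The median change of all genes was 0.03 and 0.04 as deposited and 0.13 and 0.16 under median centring. Among the lists called, the G2/M median lay at the 100th percentile of random lists matched on signal level in both lines, the S phase and MAPK medians at the 0th, the medians of the MYC list at 0.01 and 0.045, those of the DNA repair list at 1.03 and 0.02 and those of the autophagy list at 99.8 and 100. The other called lists were not extreme in each line: the synthetase medians lay at the percentiles 22.2 and 0, the fatty acid medians at 0.19 and 23.6 and the ER medians at 5.15 and 38.9.

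**Figure D4:**
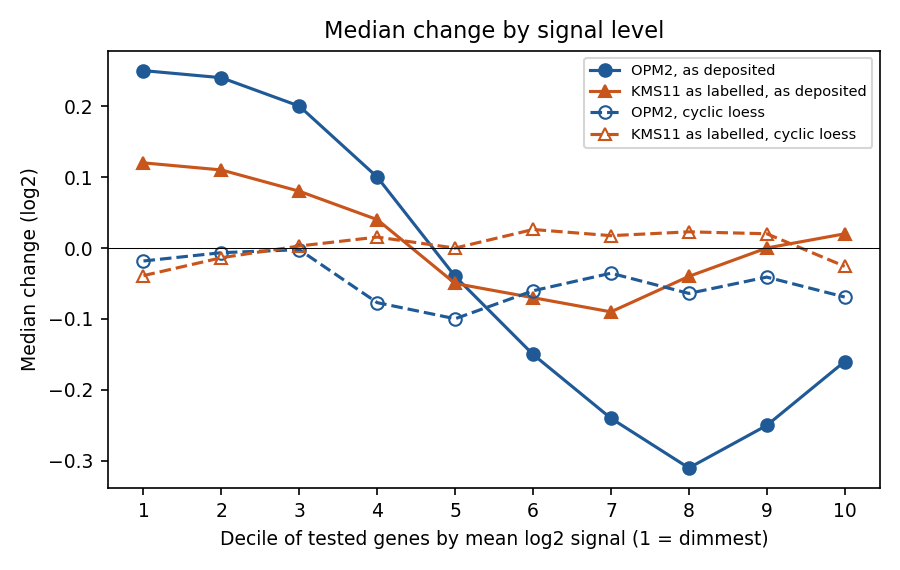
The median log2 change (y axis) is plotted for each decile of the tested genes by mean signal (x axis, 1 for the dimmest), circles for OPM2 and triangles for the KMS11-labelled arrays, filled for values as deposited and open for values after cyclic loess. The OPM2 line falls from 0.25 to -0.31 and lies between -0.10 and 0.00 after cyclic loess.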

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

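The tests of the brightest genes, of myeloid markers and of cyclic loess scaling in this part were chosen after the results were seen, and none of the differences between lines below was tested, since each line has 1 array per treatment.

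PIM1, a kinase gene, went opposite ways, with a KMS11-labelled minus OPM2 difference of -3.44. STON2 differed the same way, with a difference of -2.85. STX11 went down in OPM2 and up on the KMS11-labelled arrays, with a difference of 2.88, of which at least 2.44 lies above background. MTMR10 had a difference of 3.16 in the same sense. CYP51A1, of the sterol pathway, had a difference of 2.69. Antigen presentation genes were low among matched random lists in OPM2 and high on the KMS11-labelled arrays, and their medians differed by 0.74. Outside the named genes, 24203 transcript clusters had no gene symbol here and passed the signal filter, and 348 of them were at least 2-fold lower in both lines, against 47.9 for independent lists, while 86 were higher, against 35.0. These counts were not bounded against background. The clusters had median changes of 0.36 in OPM2 and 0.04 on the KMS11-labelled arrays, with 2772 and 306 at least 2-fold higher.

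On the OPM2 arrays dim genes read higher and bright genes lower after treatment, and the NF-kB and sterol lists differed between the lines. Olfactory receptor genes, which these cells should not use, had a median OPM2 change of 0.49 (0.44 to 0.54 over 392 genes), as a raised background or compressed signal on the treated array would give, and this remains a candidate explanation. The brightest decile of genes had a median OPM2 change of -0.16 (-0.19 to -0.12), and a true fall of abundant transcripts cannot be told apart from compression there, since both lower the same genes on 1 array. A trend of the mean change with signal level does not by itself account for the list differences. After cyclic loess, which removes that trend, the G2/M median still exceeded the S phase median by 1.39 (1.18 to 1.74) in the line with the smaller gap. The KMS11-labelled change still exceeded the OPM2 change by 0.917 (0.280 to 1.67) over NF-kB targets and by 0.642 (0.166 to 1.16) without TNFAIP3. Over cholesterol genes it did so by 1.07 (0.731 to 1.42). These intervals are over list members, not arrays, and cyclic loess cannot restore changes hidden under a raised background. On the treated OPM2 array 40 of 42 G2/M, 37 of 40 S phase and 16 of 20 cholesterol genes lay above background. Only 9 of 18 NF-kB targets did, so compression stays open for that list. More myeloid cells in the treated KMS11-labelled culture cannot be told apart from a response of the cells for the NF-kB list. Myeloid markers had a median change of 0.09 (-0.06 to 0.22), but 8 of the 11 already lay above background on the control array, LYZ at 13.44, which would hide an added share. A difference in response between the cells behind the labels also stays open, untested.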

How the results depend on the processing

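Cyclic loess was chosen after the data were seen and the other alternatives before. The tests of called results kept their direction under all of them that gave one. Medians did change sign. The KMS11-labelled median of the called ER list, -0.04 as deposited, was 0.07 under quantile normalization and 0.08 under median centring. Among lists not called, the Wnt median over both lines, 0.085 as deposited, was -0.09 under quantile normalization and -0.575 with the lowest 50% of genes left out. Medians over both lines also changed sign for p53 targets (0.03) and the BCL2 family (0.005) under median centring. So did those of stromal markers (-0.02 under quantile normalization) and immediate early genes (-0.1 with the lowest 50% left out). For the treatment every fit gave 0 genes past an adjusted p of 0.05 in either direction. Leaving out a line leaves no residual degrees of freedom, so it gave values for genes and list medians but none for gene counts or list tests, and a line can only be read alone. The MAPK, S phase, G2/M, DNA repair, autophagy and MYC lists passed under all 8 changes of scaling, filter, clusters and block, with adjusted p of at most 0.00267. Under quantile normalization 553 genes were at least 2-fold lower in OPM2, 90 were higher and 108 lower in both lines, 4 lists were lower, and adjusted p was 0.0773 for aminoacyl-tRNA synthetases, 0.353 for the ER list and 0.0941 for fatty acid synthesis. Under median centring 83 genes were higher and 130 lower in both lines. Without a filter rho was 0.319, 11 lists were lower, and the line difference of myeloid markers had adjusted p = 0.131. With the lowest 50% left out rho was 0.368, 4 lists were lower, and adjusted p was 0.0988 for the synthetases, 0.452 for the ER list and 0.189 for fatty acid synthesis. Without the line block the ER list had adjusted p = 0.131. At 1.5-fold 282 genes were higher and 822 lower in both lines and 158 went opposite ways, against 109.4, 293.5 and 358.6 for independent lists. Under cyclic loess 569 genes were lower in OPM2 and 123 lower in both lines, and adjusted p was 0.347 for the ER list and 0.125 for fatty acid synthesis. With an estimated correlation 0 lists were higher and 0 lower, each called list had adjusted p = 0.894, and the plasma cell, myeloid and erythroid line differences had 0.981. With 1 residual degree of freedom that test could hardly have come out otherwise, so it does not decide on the calls. By fry, which asks another question, 0 and 0 passed, with adjusted p = 0.693 for the MAPK, S phase, G2/M, DNA repair, autophagy and MYC lists, 0.747 for the synthetases and 0.771 for the ER and fatty acid lists. The stricter filters and block tests change the genes or residuals used, and otherwise the cause was not tested. The other values recomputed were changes of named genes, list medians, lists not called and further line differences. Of these, 1643 were counted as unchanged, 47 moved by more than the spread between lines, 9 lost and 11 gained a call. The 9 were all line differences of lists. Changes of named genes counted as unchanged wherever they gained no call, and always with a line left out. For them the tally says nothing about how far the values moved. On the treated OPM2 array the background, at 7.65 for the 95th percentile of olfactory receptor genes against 6.81 in the control, limits what dim genes can show.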

Other observations

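In this part the tests of cell identity, of histones and of lists drawn up from the leading genes were chosen after the results that prompted them were seen.

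HBP1, KLHL24 and ARRDC3 were among the leading genes higher in both lines, and a list of known targets of FOXO transcription factors, which restrain growth when growth factor signalling is low, was drawn up for that reason. Of its 19 tested members 11 were higher in both lines and 2 lower, and none passed over all genes. Only 8 lay above background on all 4 arrays, 6 of them higher in both lines and 0 lower. Among these SESN3 was higher by 0.54 and 1.34, CITED2 by 0.63 and 0.53 and the MYC antagonist MXI1 by 0.48 and 0.41, OPM2 before the KMS11-labelled arrays. Against them stood TNFSF10 (-0.76 on the KMS11-labelled arrays) and FOXO1 itself (-1.21 in OPM2). The median over both lines was 0.35, at the 99.99th percentile of 10000 matched random lists, and 0.34 at the 99.97th percentile for the 15 members in no fixed list. Higher levels of some FOXO targets may therefore accompany treatment, as a hypothesis found and tested on the same arrays.

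A like idea for splicing regulators failed. CLK1 was higher by 2.25 and 1.67 and CLK4 by 0.81 and 0.73, but 12 tested genes of SR proteins and CLK kinases had a median over both lines of -0.255, at the 17.3th percentile of matched random lists. SRSF1 stood at -1.02 and -2.28, TRA2B at -0.60 and -1.58 and SRSF5 at 0.19 and -1.42.

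The arrays labelled KMS11 carry some erythroid and myeloid genes, GATA1, RHAG and MS4A3 among them, at high levels and have many plasma cell genes low. Of 25 plasma cell identity genes 14 lay above background on the KMS11 control array, JCHAIN at 9.94 among them, and of 10 erythroid and megakaryocyte markers 4 did. Erythroid or myeloid cells as the smaller part of a plasma cell culture would lower plasma cell genes by less than 1 log2 unit, yet the 21 identity genes above background on at least 1 control array had a median difference of -2.36 (-5.08 to -1.56), KMS11-labelled minus OPM2 on the control arrays, if OPM2 stands for plasma cells. Over all 25, with the 4 under background on both arrays, it was -1.97 (-3.24 to -0.67), an interval that reaches above -1. The filter to 21 admits more genes through OPM2, where 20 lay above background on the control array. Both sets also hold IRF4, PRDM1, POU2AF1, TNFRSF17 and JCHAIN, whose low values prompted the question. The comparison therefore does not decide against such a mixture. Labels exchanged between the lines stay open: MAF, which KMS11 cells are known to overexpress, read 12.11 on the OPM2 control array, though an exchange alone would not bring erythroid genes to either line, both being known as plasma cell lines. MAF read 5.68 on the KMS11 control array, so cells other than KMS11 under its label are a candidate explanation. A KMS11 culture that lost its plasma cell program, or a small share of plasma cells among others, stays open, since no test of identity such as genotype was run here.

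G2/M genes were higher and S phase genes lower in both lines. Fewer cells in S phase may be part of this, and replication-dependent histones, which are made in S phase, would then be lower. On the KMS11-labelled arrays their median change was 0.43 (0.20 to 0.74 over 17 genes), not the fall that this explanation predicts. That value rests on 17 of 40 listed histones and 1 array per treatment, and the S phase list fell there (median -0.585), so it does not decide the question. In OPM2 the histone median was -0.30 (-0.55 to 0.13), so there the explanation cannot be told apart from no change in S phase cells, with 17 genes and members on either side. A larger share of cells in G2 or mitosis stays open and was not tested.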
